A study of Mus musculus with 20 samples.

How the data were processed

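RNA was sequenced from sorted mouse type 1 conventional dendritic cells (cDC1s), the dendritic cells that carry XCR1 and cross-present antigen to CD8 T cells. The 20 libraries fell into 8 groups, taken from the sample titles, and came in 3 tables that were each tested apart, since they were counted separately. The first table held cDC1s from untreated mice and from mice given total lymphoid irradiation with anti-thymocyte serum (TLI/ATS), 2 libraries per group. The second held the EpoR+ and EpoR- fractions of cDC1s after TLI/ATS, 2 libraries per group, in which a tdTomato reporter marked the erythropoietin receptor. The third held cDC1s of the spleen and of the peripheral lymph nodes from Epor flox/flox control mice and from mice in which Xcr1-Cre deletes Epor (cKO), 3 libraries per group.

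Every value analysed was a raw read count per gene, deposited by the authors as whole numbers without normalization. Per the submitters' processing notes, reads of the first table passed through HISAT2, SAMtools, StringTie and featureCounts on GRCm38, with versions not given in the sources used here. Per the file headers, reads of the second table were counted with featureCounts 2.0.3 in paired-end mode without counting read pairs as fragments, so a pair can add 2 counts, and without strand. Per the file headers and the submitters' processing notes, the third table came from HISAT2 2.1.0 and from featureCounts 2.0.8 on the Ensembl GRCm38 annotation release 100, with both ends required to map, chimeric pairs left out and again no counting of pairs as fragments. Per the labels' protocols, libraries of the third table were made from 10 ng of RNA with a full-length poly(A) kit and 150 pg of cDNA went into tagmentation. Amplified reads carry no molecular identifiers in these tables, so no interval or floor given here covers more than counting error. Each interval and floor treats every count as independent. This does not hold for the EpoR+, EpoR-, spleen and lymph node libraries, where a pair can add 2 counts. For these libraries the intervals are too narrow even for counting error, and folds given as "at least" can be too high.

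Gene identifiers were paired with symbols from the tables or from the GENCODE vM21 annotation of GRCm38. A symbol was found for 98.9% of 47729 genes in the first table, 99.8% of 54532 in the second and 99.4% of 55487 in the third. Coordinates are those of GRCm38, counted from 1. Of 302 named genes in the annotation, 81 shared exon bases with another gene and 9 shared over 25% of them, which makes their counts uncertain. Among these 9 the partner lay on the same strand for Amy1, Smr3a, Ctsd, Itgam, Ifng, Rab43 and S100a4 and on the opposite strand for Nop9 and Rfxank. Near-identical copies can also exchange reads, which touches Hba-a1 and Hba-a2, Hspa1a and Hspa1b, the ribosomal protein genes with their many pseudogenes, and the immunoglobulin segments.

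Total counts per library (M, counts times 1e-06) were 77.6 and 67.3 M after TLI/ATS, 46.2 and 40.6 M in untreated cDC1s, 37.3 and 37.9 M in EpoR+ and 40.1 and 33.7 M in EpoR- cDC1s. Spleen controls had 35.7, 26.6 and 35.5 M, spleen cKO 44.6, 32.2 and 34.4 M, lymph node controls 40.8, 41.0 and 37.0 M and lymph node cKO 42.6, 38.6 and 49.7 M. At these depths a floor of 3 counts lay between 0.0384 and 0.12 CPM per library, CPM being counts scaled to the depth of the library.

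Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), scaled by TMM and tested with edgeR's quasi-likelihood test with robust dispersion, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no fold cut-off. The first and second tables were fitted on their own 4 libraries. The third was fitted on all its libraries with a mean per group, and from that fit came cKO against control in each tissue, the difference of that effect between the tissues, and lymph node against spleen in each genotype. The sort gate differed between the tissues (CCR7+XCR1+SIRPa- in spleen, migratory XCR1+SIRPa- in lymph node), so the tissue comparisons are also comparisons of gates. Log2 fold changes are given with their standard error (SE). CPM are given as mean ± SD.

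The 33 gene lists, 12 of them markers of other cells, were fixed before the data were examined, as were the tests, the thresholds, the alternatives and the rule for named genes. A list with at least 5 tested members was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. Named genes were Epor and the sort genes Xcr1, Cd8a, Sirpa and Ccr7 in every comparison; up to 8 genes per direction with the largest fold change among those past the threshold with a mean of at least 3 log2 CPM and no overlap between groups, leaving out predicted models, pseudogenes, receptor segments and mitochondrial genes; 5 per direction for the difference of the cKO effect; and up to 4 members, 2 per direction, of each list with at least 3 members past the threshold or a camera adjusted p under it. List members that did not pass the test are not named. That separation was made after their values were seen, as were the choice of a list of salivary gland genes, a list of pancreatic enzyme genes, the parting of libraries at 60% even counts among counts from 1 to 10, and the thresholds for V segments. Any other gene named outside the rule is said to be so.

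The method was tested on simulated counts drawn from the means and depths of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold. For TLI/ATS against untreated (16594 genes) it recovered 9 and 66 of them, and 14 of 89 calls were unchanged genes. For EpoR+ against EpoR- (15097 genes) it recovered 17 and 69, with 19 of 105 calls unchanged. For the cKO effect it recovered 44 and 64 in spleen (16766 genes; 6 of 114 calls unchanged) and 41 and 57 in lymph node (16800 genes; 11 of 109). For the difference of these effects (16798 genes) it recovered 13 and 42, with 2 of 57 unchanged, and for lymph node against spleen in control mice (16837 genes) 35 and 50, with 5 of 90. Several of these false shares lie above the nominal 5%. In each of the 6 simulations 0 of 30 unchanged lists were called and the shifted list was called. Genes were drawn independently there, so this does not show how the list tests behave where members of a list correlate.

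The alternatives were DESeq2 1.42.0, DESeq2 size factors in place of TMM, no filter, a filter at 50 counts, leaving out the 20 most counted genes, each library left out in turn, a fit of only the libraries compared, and a replicate block. Further alternatives were chosen after seeing the data. Immunoglobulin and T cell receptor segments were left out, and in another fit genes of other cells. Spleen control replicates 1 and 2, which stood apart from the other spleen libraries by chi-square per degree of freedom, were left out. A term for the library set was added. Lymph node against spleen in cKO mice was run under the alternatives listed for control mice. The labels do not say that a replicate number marks a mouse or a day, nor that libraries of a group came from different mice, so p-values measure only the spread between these libraries, which may be technical. Replicate libraries differed by far more than sampling noise (chi-square per degree of freedom 16.2 or more in every pair of a group), so each was counted once.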

Results

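Gene expression was measured by RNA sequencing in cDC1s sorted from mice. The aim was to follow how these dendritic cells change after a tolerance-inducing treatment and what the erythropoietin receptor (EpoR) does in them. The libraries comprised XCR1+CD8a+ cDC1s of wild-type C57BL/6 mice, untreated or on day 15 of TLI/ATS (n = 2 each), and EpoR+ and EpoR- cDC1s on day 15 of TLI/ATS (n = 2 each). They also comprised cDC1s of the spleen and peripheral lymph nodes of control and Epor cKO mice (n = 3 in each of 4 groups). Depth ran from 40.6 to 77.6 M counts in the first set, from 33.7 to 40.1 M in the second and from 26.6 to 49.7 M in the third.

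The targeted gene was examined first. Epor (ENSMUSG00000006235; chromosome 9, 21958897 to 21963506, minus strand), which encodes the receptor that carries the erythropoietin signal through JAK2 and STAT5, had 236 and 127 counts in the TLI/ATS libraries and 0 in both untreated libraries. That is at least 78.6-fold higher after treatment, against a floor of 3 counts over the group. In the EpoR+ fraction it had 525 and 657 counts (15.6 ± 2.24 CPM) and in the EpoR- fraction 4 and 11 (0.214 ± 0.16 CPM), a 76.4-fold difference with a 95% counting interval from 46.1 to 137. Lymph node controls had 24, 28 and 4 counts and lymph node cKO libraries 0, 0 and 0. That is at least 20.4-fold lower if every count is taken as independent, and the bound is lower where pairs add 2 counts. Spleen controls had 1, 0 and 6 counts and spleen cKO libraries 0, 2 and 0, a cKO to control ratio of 0.244 with an interval from 0.0247 to 1.28. Loss of Epor was not detectable in spleen at this depth. The filter on low counts took Epor out of the test of the spleen and lymph node libraries, in which these counts stand without an adjusted p. The reads that remain after a Cre deletion depend on which exons were flanked by loxP sites, not given in the sources used here.

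**Figure D1:**
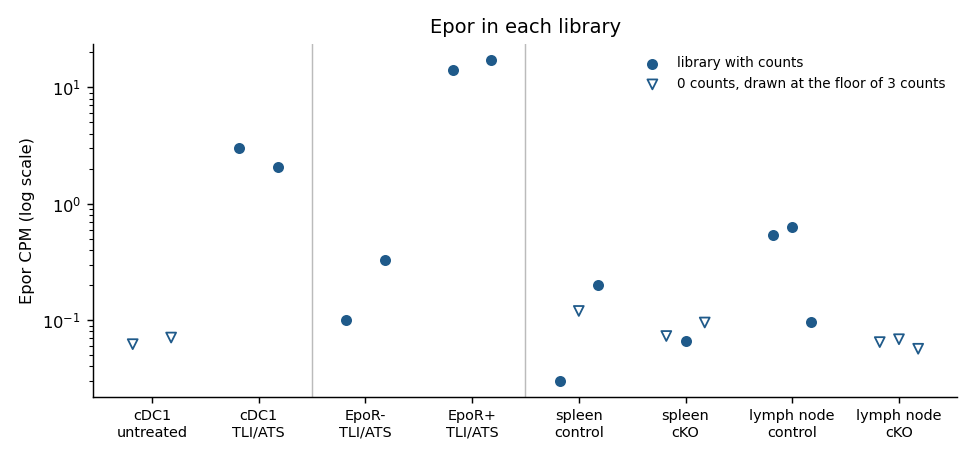
Epor in each library, in CPM on a log axis, with 1 point per library and an open triangle at the floor of 3 counts for a library with 0 counts. EpoR+ libraries reach 14 and 17.2 CPM, TLI/ATS libraries 3.02 and 2.07 CPM, and all 3 lymph node cKO libraries have 0 counts.

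The first comparison asked what TLI/ATS does to cDC1s. C1qb, a chain of complement C1q, stood at 190 ± 4.92 against 12.7 ± 1.77 CPM (log2 fold change 3.90 ± 0.20 SE, n = 2 each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0039). C1qa rose by 3.58 and Fcna, a ficolin of splenic macrophages, by 3.80. Lpl, lipoprotein lipase, rose by 4.72 ± 0.39. Lymphoid genes moved the other way, and whether their RNA came from cDC1s or from other cells in the sort was not tested. Lef1, a transcription factor of T cells, fell from 35.3 ± 0.241 to 0.37 ± 0.0531 CPM (log2 fold change -6.58 ± 0.27). Fcer2a, the low-affinity IgE receptor of B cells, changed by -6.24 and S1pr1, the receptor by which lymphocytes leave lymphoid organs, by -5.28. The genes of the sort did not pass the threshold: Xcr1 changed by 0.44 ± 0.15 (adjusted p = 0.256), Cd8a by -0.06 ± 0.17, Sirpa by 0.40 ± 0.58 and Ccr7, the chemokine receptor of migrating dendritic cells, by -0.82 ± 0.18 (adjusted p = 0.109).

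Among the remaining genes named by size of change, Ccr3 (4.28), Ptgs1 (3.72), C1qc (3.69) and the basophil protease gene Prss34 (4.24 ± 0.62) rose. Dapl1 (-6.86), Skap1 (-6.23), Klk1 (-6.15), Smim5 (-5.88), D13Ertd608e (-5.78) and Gimap4 (-5.74) fell. Marker lists of other cells shifted too, for which the cell of origin was not tested either. Of 21 T cell markers 20 fell (21 adjusted over the list alone; list median -5.39), with Cd8b1 at -5.55 and Trbc2 at -5.68. Of 18 B cell markers 15 fell (16 over the list alone; median -4.17), with Cd79a at -4.58. Of 16 plasmacytoid dendritic cell markers 13 fell (15 over the list alone; median -2.98), with Siglech at -4.65. These 3 lists held with an estimated correlation (adjusted p = 0.0298 for each). Of 16 NK cell markers 4 fell, with Nkg7 at -4.72 (adjusted p = 0.153 with an estimated correlation). Of 23 markers of cDC2s and monocyte-derived cells 7 fell and 1 rose (Dtx1 -4.52, Fcgr1 3.82; adjusted p = 0.141 with an estimated correlation). Of 23 macrophage markers 12 rose (21 over the list alone; median 2.77; adjusted p = 0.141 with an estimated correlation). Of 24 erythroid markers 7 rose (median 2.21; adjusted p = 0.141 with an estimated correlation), with the alpha globin genes Hba-a1 and Hba-a2 both at 2.93. Neutrophil and monocyte markers went both ways, 4 of 17 rising and 2 falling (S100a9 2.50, S100a8 2.30, Ly6c2 -3.47, Ms4a4c -1.47; adjusted p = 0.358 with an estimated correlation). Of 11 platelet and mast cell markers 2 rose, among them Mcpt8 at 3.60 (adjusted p = 0.149 with an estimated correlation). Of the plasma cell markers 2 of 15 fell, of the stromal and endothelial markers 1 of 12, and of the Langerhans cell and keratinocyte markers 0 of 5 passed (17236 genes tested in all, 2705 with an unadjusted p under 0.05).

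Of 29 cDC1 identity genes 1 passed (6 over the list alone), Sept3 with a rise of 1.17 ± 0.16, and the list median was 0.41 (adjusted p = 0.141 with an estimated correlation). Of 50 genes of CCR7-linked maturation 5 fell (11 over the list alone), among them Apol7c (-1.28 ± 0.16) and the chemokine gene Ccl5 (-1.27 ± 0.16; list adjusted p = 0.187 with an estimated correlation). Of 52 cell cycle genes 3 rose over all genes and 47 over the list alone, among them Ccnb2, a mitotic cyclin (1.18 ± 0.17), and Cdc20, an activator of the anaphase-promoting complex (1.04 ± 0.16; list median 0.82; adjusted p = 0.149 with an estimated correlation). The list of apoptotic cell uptake had 6 of 45 genes higher and 2 lower. Its risen members include the complement genes C1qa and C1qc, while the phosphatidylserine receptor gene Havcr1 (-2.96) and the integrin gene Itgb3 (-3.37) fell (adjusted p = 0.408 with an estimated correlation). In the list of JAK2-STAT5 responses 3 of 25 genes fell, among them the kinase gene Pim2 (-1.61 ± 0.19) and the caspase inhibitor gene Xiap (-1.56 ± 0.21), and the list did not pass camera (adjusted p = 0.137). Isg15, a ubiquitin-like interferon response gene, rose by 1.38 ± 0.17 as the only one of 54 interferon-stimulated genes past the threshold (5 rose and 2 fell over the list alone; adjusted p = 0.643 with an estimated correlation). The lymphocyte cytokine genes Ltb (-2.56) and Ifng (-4.90) fell among 4 of 31 inflammatory genes, a list with a median of 0.04, a mean of -0.52 and no call (camera adjusted p = 0.0914). Ikbke (-5.36) fell as 1 of 27 genes of NF-kB signalling (adjusted p = 0.588 with an estimated correlation), and S1pr4 (-2.27) fell with S1pr1 among 4 of 40 genes of migration and adhesion. Of the regulatory and Treg-inducing genes 1 of 37 rose and of the p53 and DNA damage genes 1 of 34. In each of the lists for MHC class I, MHC class II (median 0.11, mean -0.09), glycolysis and lysosome 1 gene fell, and 2 of 32 immediate early genes fell. No gene passed edgeR's quasi-likelihood test in the lists of cholesterol synthesis and ribosomal proteins, nor in those of the unfolded protein response, oxidative phosphorylation and mitochondrially encoded genes (adjusted p = 0.408, 0.806 and 0.781 with an estimated correlation).

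In all 465 of 17236 genes passed, 86 higher and 379 lower after TLI/ATS, and 49 of them were immunoglobulin or T cell receptor segments (47 lower). The groups did not overlap for 47.5% of genes, against 33.3% by chance. By chi-square per degree of freedom the TLI/ATS libraries differed more from each other (365) than from the untreated libraries (208 to 253). The untreated pair stood at 17.5. By correlation of log2 CPM the TLI/ATS pair was closer (r = 0.978, against 0.966 to 0.968 across groups). Without replicate 1 or 2 of the TLI/ATS group the spread was estimated from the untreated pair alone. More genes passed then, but on too small a spread, so this does not speak for more changes. With the genes of other cells left out 302 passed. DESeq2 called 1414 (450 higher, 964 lower).

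The second comparison asked what distinguishes EpoR+ from EpoR- cDC1s after TLI/ATS. C1qa stood at 1540 ± 45.5 against 15.6 ± 0.342 CPM (log2 fold change 6.63 ± 0.12, n = 2 each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.62e-05). Vcam1, an adhesion molecule of splenic red pulp macrophages, stood at 4110 ± 161 against 44.4 ± 3.82 CPM (6.53 ± 0.13), and Hmox1, the haem-degrading enzyme, at 3340 ± 103 against 89.1 ± 2.31 CPM (5.23 ± 0.11). Csf1r, the receptor of macrophage colony-stimulating factor, rose by 6.11 ± 0.17. The sort genes shifted too. Xcr1 fell by 1.29 on the log2 scale (451 ± 60.2 against 1110 ± 65.8 CPM; adjusted p = 0.00243), Cd8a changed by -1.10 ± 0.10, and Sirpa, a receptor of cDC2s and macrophages, rose by 5.94 ± 0.20 (1790 ± 78.3 against 29.1 ± 6.24 CPM), while Ccr7 did not pass (0.45 ± 0.20, adjusted p = 0.199).

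Of 24 macrophage markers all 24 rose (median 6.41), Fcna by 6.75 among them (adjusted p = 0.0749 with an estimated correlation). No list in this comparison held with an estimated correlation. Of 26 erythroid markers 23 rose (median 3.46; adjusted p = 0.0941 with an estimated correlation), including the biliverdin reductase gene Blvrb (4.29) and Ermap (4.28). Macrophages that recycle red cells express part of this list too. Of 22 markers of cDC2s and monocyte-derived cells 15 rose and 1 fell (Fcgr1 6.61, Ccr2 -0.75; adjusted p = 0.129 with an estimated correlation). The uptake and degradation programs moved with them. Of 47 genes of apoptotic cell uptake 27 rose and 4 fell (C1qc 6.74, Clec9a -1.24; adjusted p = 0.129 with an estimated correlation), and of 40 lysosome and autophagy genes 28 rose and 1 fell, with the cathepsin genes Ctsd at 5.55 and Ctsb at 3.53 and the glucuronidase gene Gusb at -0.74 (adjusted p = 0.205 with an estimated correlation). Of 54 interferon-stimulated genes 30 rose and 3 fell, among them Ifit3 (4.26 ± 0.23), Ddx58 (3.28 ± 0.15), Ifi205 (-1.08) and Phf11b (-0.79; adjusted p = 0.556 with an estimated correlation). Of 39 regulatory and Treg-inducing genes 11 rose and 2 fell, with Hmox1 and the checkpoint gene Vsir (1.33 ± 0.10) higher and Havcr2 (-1.18) and Btla (-1.25) lower (adjusted p = 0.648 with an estimated correlation).

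Genes of cDC1 identity were lower in EpoR+ cells, 23 of 29 (24 over the list alone; median -1.09; adjusted p = 0.268 with an estimated correlation), such as Clec9a, the receptor by which cDC1s recognise dead cells (262 ± 21.3 against 619 ± 51.6 CPM, -1.24 ± 0.12), and Sept3 (-1.27). Wdfy4, needed for cross-presentation by cDC1s, changed by -1.13 ± 0.10 among 8 lower and 2 higher of 32 genes of MHC class I and cross-presentation, and the NADPH oxidase gene Cybb rose by 3.61 there. Of 21 MHC class II genes 10 fell and 4 rose, with a median of -0.58, a mean of 0.16 and no call (camera adjusted p = 0.594). Ciita, the class II transactivator (-1.10), and H2-Eb1 (-0.82) were lower, and the protease genes Lgmn (4.66) and Ctsb were higher. Of 88 ribosomal protein genes 36 fell (Rpl34 -0.74; adjusted p = 0.951 with an estimated correlation). The list of JAK2-STAT5 responses had 5 of 25 genes higher and 2 lower, with the feedback inhibitor gene Socs2 (1.83 ± 0.21) and the transferrin receptor gene Tfrc (1.42 ± 0.16) up and Jak2 (-0.77 ± 0.10) and Ccnd1 (-0.71) down (camera adjusted p = 0.754). Of 49 genes of CCR7-linked maturation 7 rose and 2 fell (Basp1 1.30, Serpinb6b -0.83). Cell cycle genes had 4 of 52 lower and 0 over the list alone (adjusted p = 0.951 with an estimated correlation), and no immediate early gene of 32 passed edgeR's test. Migration and adhesion went both ways, 9 up and 13 down of 41 (Itgam 2.91, Adam19 -1.11, Itgb7 -1.03).

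Among genes with at least 3 log2 CPM on average and no overlap between groups, predicted or unnamed models and pseudogenes left out, the largest rises were those of Tenm4 (8.29), Tmem229a (8.13), Adrb1 (8.12), Sema6a (7.99), Ksr2 (7.90), Mmp13 (7.38), Erbb2 (7.36) and Mrap (7.27), each at 0.212 CPM or less in EpoR- cells. The falls under the same limits ran from Clec1a (-1.64 ± 0.16) through Naalad2 (-1.59), Tmem231 (-1.50), Itm2a (-1.48), Plce1 (-1.45), Clnk (-1.44) and Itga8 (-1.42) to Mmp28 (-1.40). Of 15627 genes tested 2606 passed, 1864 higher and 742 lower in EpoR+ cells. With a replicate block, for libraries that the labels do not pair, 5347 passed, 3077 higher and 2270 lower. The balance of directions therefore depends on the fit. Groups did not overlap for 58.2% of genes, against 33.3% by chance. Without EpoR+ replicate 1 1496 genes passed and without EpoR+ replicate 2 1454. Pancreatic enzyme genes summed to 2640 CPM in EpoR- replicate 1 and to 186 CPM or less in the other 3 libraries. Their fold changes did not pass the threshold.

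**Figure D2:**
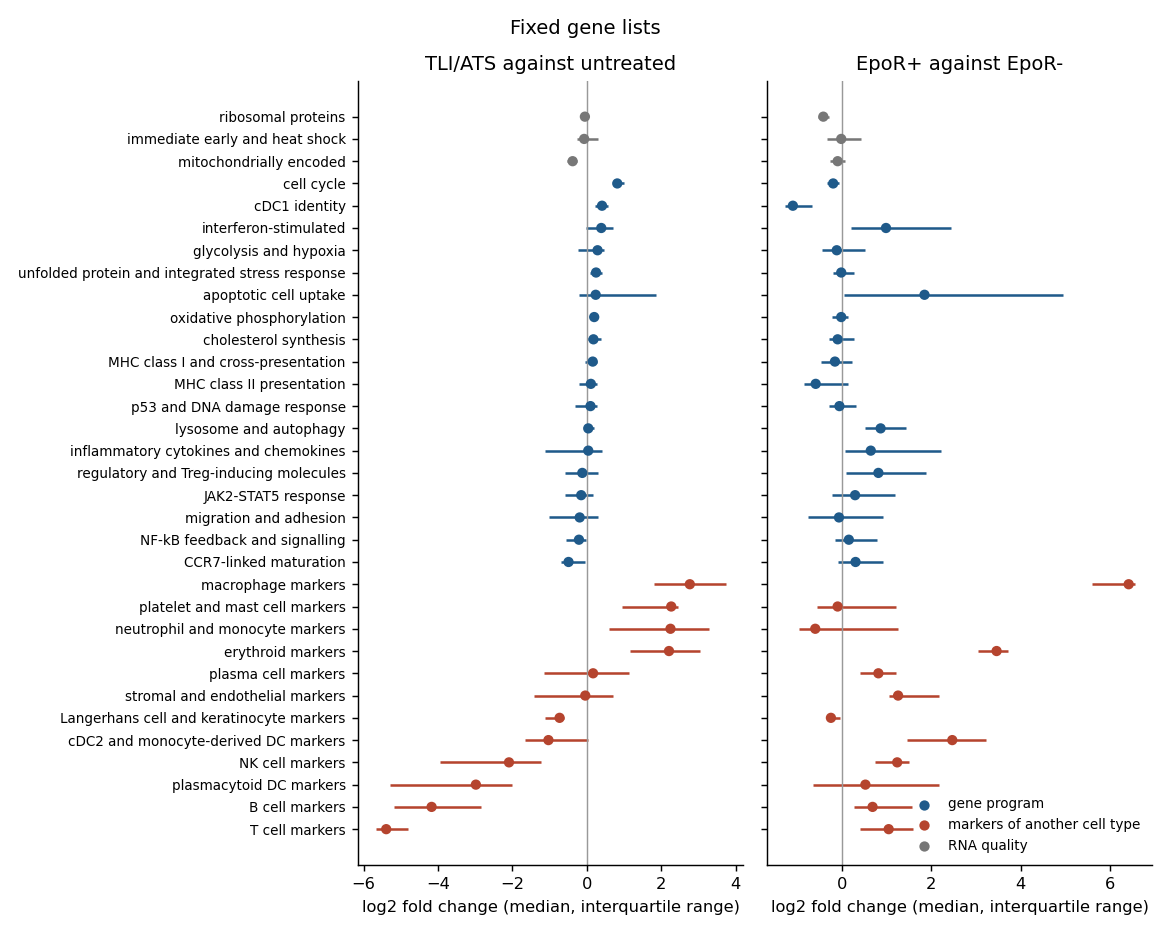
Median log2 fold change of the fixed gene lists with the interquartile range of their members, for TLI/ATS against untreated (left) and EpoR+ against EpoR- cDC1s (right), coloured by the kind of list. T cell markers lie lowest on the left (median -5.39) and macrophage markers highest on the right (median 6.41).

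**Figure D3:**
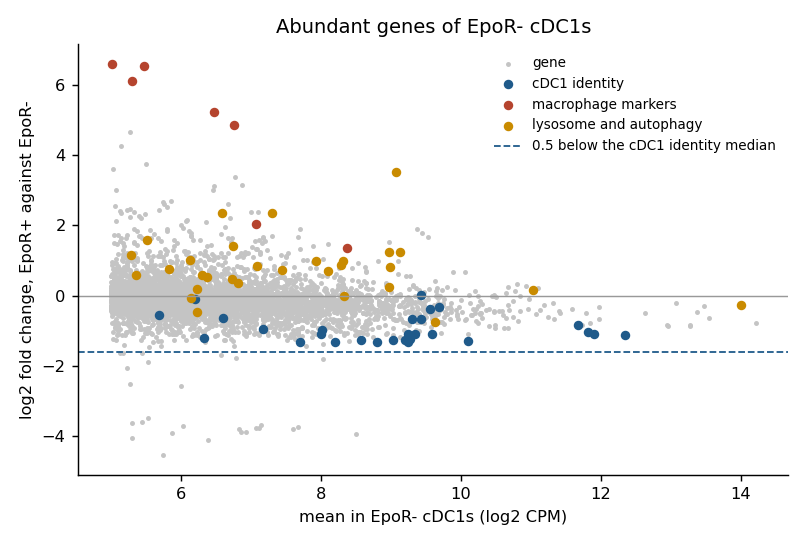
Log2 fold change of EpoR+ against EpoR- cDC1s for the 5349 genes with at least 5 log2 CPM in EpoR- cells, against their mean log2 CPM in EpoR- cells; the dashed line lies 0.5 below the median of the cDC1 identity list. Of 637 genes that fell 4 lie below the line at -1.59, and 23 more genes below it did not pass the threshold.

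The third set compared cDC1s of cKO and control mice in each tissue. The controls are named only as flox/flox, so effects of Cre could not be told apart from those of Epor. In spleen, immunoglobulin genes and a small set of others were higher in cKO libraries. Whether the RNA of antibody genes came from cDC1s or from other cells in the sort was not tested. Jchain, the joining chain of secreted antibodies (ENSMUSG00000067149; chromosome 5, 88519809 to 88527891), stood at 750 ± 15.1 against 369 ± 20.7 CPM (log2 fold change 1.02 ± 0.07, n = 3 each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.61e-06). The kappa constant gene Igkc rose by 1.13 ± 0.08 and Ighg2b by 4.97 ± 0.35. Igfbp4, which binds insulin-like growth factors, rose by 2.70 ± 0.51 from a low level (0.494 ± 0.41 to 3.14 ± 0.403 CPM), Ms4a4b by 2.46 ± 0.43 and Acap1 by 1.58 ± 0.31. Hspb1, a small heat shock protein, fell from 50.6 ± 2.76 to 24.9 ± 2.19 CPM (-1.02 ± 0.14), and Hsph1 (-0.61 ± 0.09) and the chaperonin gene Hspe1 (-0.56 ± 0.09) fell with it. Spic, a transcription factor of red pulp macrophages (chromosome 10, 88674772 to 88685015), changed by -0.76 ± 0.15 (45.1 ± 4.14 against 76.5 ± 11.5 CPM). Xcr1 (-0.27, adjusted p = 0.463), Cd8a (-0.20), Sirpa (0.21) and Ccr7 (0.17) did not pass.

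Rhbdf1 (1.29), Unc119 (1.08), Nop9 (1.07) and Mtmr9 (1.01) also rose in spleen, and the noncoding RNAs Rn7sk (-1.09) and Malat1 (-0.68), Gpalpp1 (-0.89) and Fnbp1l (-0.62) fell. The cell of origin was not tested for the plasma cell and B cell markers that follow. Of 15 plasma cell markers 4 rose (8 over the list alone; adjusted p = 7.39e-05 with an estimated correlation) and of 18 B cell markers 1 rose (5 over the list alone; adjusted p = 0.0135 with an estimated correlation). No cell cycle gene of 52 passed over all genes with edgeR and 6 were higher over the list alone (list median 0.40; adjusted p = 0.0234 with an estimated correlation). Of 29 cDC1 identity genes 4 rose (8 rose and 1 fell over the list alone), among them the small GTPase gene Rab7b (0.60) and the acid amidase gene Naaa (0.58; adjusted p = 0.0601 with an estimated correlation). Xbp1, a transcription factor of the unfolded protein response that plasma cells also express strongly, rose by 0.68 (1 of 34; adjusted p = 0.158 with an estimated correlation). The lactate dehydrogenase gene Ldha rose by 0.57 (1 of 30; adjusted p = 0.321 with an estimated correlation). The integrin genes Itgb2 (0.88) and Itgb7 (0.76) rose among 3 of 38 genes of migration and adhesion (adjusted p = 0.347 with an estimated correlation). Immediate early and heat shock genes had 2 of 32 lower (1 higher and 7 lower over the list alone; adjusted p = 0.128 with an estimated correlation). Ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes had medians of -0.34, -0.12 and -0.45 without a gene past edgeR's test (adjusted p = 0.321, 0.34 and 0.347 with an estimated correlation). Mitochondrial genes made up 1.74, 1.66 and 1.08% of counts in spleen control replicates 1, 2 and 3 and 0.79 to 0.96% in the spleen cKO libraries.

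In spleen 106 of 17362 genes passed, 85 higher and 21 lower, and 36 of them were receptor segments (33 higher). Groups did not overlap for 18% of genes, against 10% by chance. Without spleen control replicate 3 379 genes passed, and without cKO replicates 1, 2 and 3 it was 33, 31 and 57. By correlation of log2 CPM spleen control replicates 1 and 2 were no closer to each other (r = 0.970) than to replicate 3 (0.973 and 0.980). With spleen control replicates 1 and 2, which stood apart from the other spleen libraries in chi-square per degree of freedom (34.7 within the pair, 123 to 210 against the others), left out 49 passed, and with the segments left out before normalization 22.

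In lymph node, genes of salivary glands parted the groups. Smr3a had 4664 counts in controls against 1 in cKO libraries (5090-fold, 95% counting interval 914 to 201000), and Bpifa2 (-10.84 ± 0.92), Chia1 (-9.57 ± 0.70) and the amylase gene Amy1 (-8.91 ± 0.73), secreted products of these glands, fell with it. A list of salivary gland genes, written after these genes were seen, had 9 of 11 tested members lower and summed to 1020 ± 322 CPM in lymph node controls and 2.37 ± 1.04 CPM in lymph node cKO libraries. The means in spleen control and cKO were 0.83 and 1.15 CPM. Whether cDC1s were the source was not tested for these genes. Apart from them, the muscle and cytoskeletal gene Tpm2 (ENSMUSG00000028464) rose from 5.54 ± 0.755 to 14.9 ± 0.947 CPM (1.43 ± 0.14, n = 3 each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 3.93e-05). Rad50, a component of the DNA double-strand break sensor MRN, rose from 118 ± 5.16 to 214 ± 10.7 CPM (0.86 ± 0.08) and Rpl29 rose by 1.36 ± 0.15. Cd8a rose by 0.51 ± 0.09 (191 ± 8.1 against 134 ± 10.9 CPM; adjusted p = 0.00993), while Xcr1 (-0.30, adjusted p = 0.705), Sirpa (-0.20) and Ccr7 (0.14) did not pass.

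Dnah2 (1.22), Asb2 (1.20), Nectin1 (1.09) and the ubiquitin ligase gene Trim25 (0.87) also rose in lymph node. Immediate early and heat shock genes split. Hspa1a (-0.78), Hspa1b (-0.72) and the AP-1 gene Jun (-0.84) fell, as did the early activation gene Cd69 (-0.88) outside that list. The nuclear receptor genes Nr4a2 (0.90) and Nr4a3 (0.85) rose. The list had 2 of 32 higher and 4 lower (2 and 11 over the list alone; adjusted p = 0.135 with an estimated correlation). Clec9a (0.62) and Cd8a rose as 2 of 29 cDC1 identity genes (6 over the list alone; adjusted p = 0.146 with an estimated correlation). Hmgcs1 of sterol synthesis rose by 0.45 as 1 of 25 (adjusted p = 0.146 with an estimated correlation). The chemokine gene Cxcl9 (0.67) and Isg15 (0.61) rose as 2 of 54 interferon-stimulated genes (adjusted p = 0.145 with an estimated correlation). Of 46 genes of apoptotic cell uptake 1 rose and 2 fell, Mfge8 (-0.64), which bridges dying cells to phagocytes, and Apoe (-0.43), and the list was not called (median 0.03; camera adjusted p = 0.872). No T cell marker of 21 passed with edgeR or over the list alone, and that list had a median of -0.45 (adjusted p = 0.302 with an estimated correlation). Cell cycle and ribosomal protein genes had medians of -0.14 and 0.17 (adjusted p = 0.208 and 0.745 with an estimated correlation). No list held with an estimated correlation in lymph node.

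In lymph node 79 of 17362 genes passed, 50 higher and 29 lower, 21 of them receptor segments. Groups did not overlap for 15.5% of genes, against 10% by chance. Without control replicate 1 51 genes passed and without cKO replicate 1 also 51. With the segments left out 49 passed and with only the 6 lymph node libraries fitted 44 (14 higher, 30 lower).

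**Figure D4:**
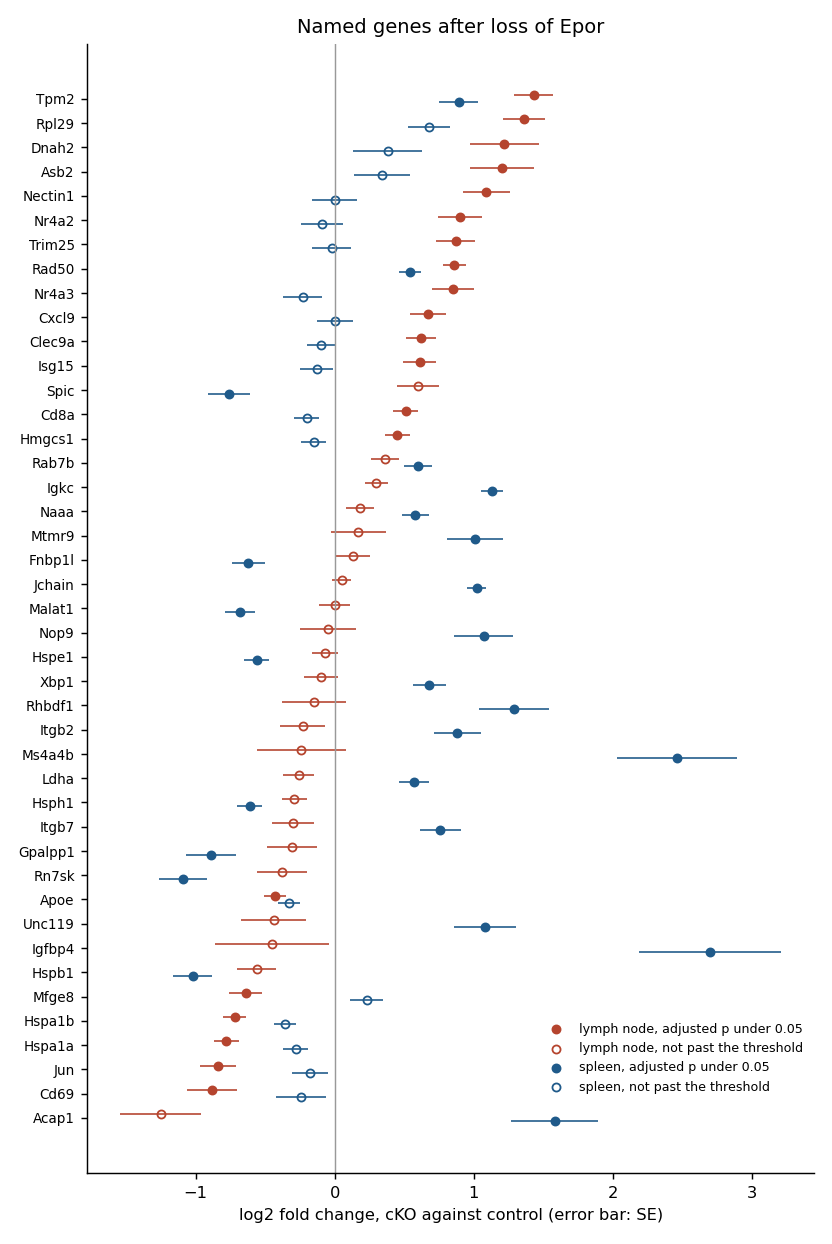
Log2 fold change of cKO against control (error bars: SE, n = 3 per group) for the named genes of the cKO comparisons in spleen and lymph node, filled where the adjusted p was under 0.05; genes with a change of 4 or more in either tissue are not drawn. Tpm2 (0.89 in spleen, 1.43 in lymph node) and Rad50 (0.54 and 0.86) are filled in both tissues.

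The effect of cKO was compared between the tissues by the difference of the log2 fold changes (lymph node minus spleen). Outside the receptor segments, 8 of which passed with a positive difference, Spic had the largest positive difference, 1.37 ± 0.21 (adjusted p = 0.0102), since it fell in spleen and stood at 21.2 ± 3.42 against 13.9 ± 1.56 CPM in lymph node. The rise of Spic in lymph node did not pass the threshold on its own. Nr4a3 (1.08 ± 0.21), the pro-apoptotic gene Bcl2l11 (0.86 ± 0.16), the ceramide synthase gene Cers6 (0.82 ± 0.16) and the NF-kB subunit gene Rel (0.76 ± 0.12) also had positive differences, with Cd8a at 0.71 ± 0.12 (adjusted p = 0.0178) and Cd274, which encodes PD-L1, at 0.63 ± 0.11. On the negative side stood the salivary gene Amy1 (-13.01), Acap1 (-2.83 ± 0.42), Ms4a4b (-2.69 ± 0.54), Tmem214 (-1.35 ± 0.22) and Cnp (-1.29 ± 0.23). The Amy1 value rests on the salivary RNA of the lymph node controls, whose source was not tested, and on 3 counts over the spleen controls. Xcr1 (-0.03), Sirpa (-0.41) and Ccr7 (-0.03) did not differ past the threshold.

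By list, 5 of 15 plasma cell markers had a lower effect in lymph node, among them Jchain (-0.98) and Iglc2 (-4.07; adjusted p = 0.00291 with an estimated correlation). So had 1 of 18 B cell markers, Igkc (-0.82, list adjusted p = 0.0277 with an estimated correlation). For neither list was the cell of origin tested. The T cell, cDC2 and neutrophil lists had medians of -0.66, -0.79 and -0.71, each with 0 genes past the threshold (adjusted p = 0.305, 0.0532 and 0.104 with an estimated correlation). Among the 12 lists of other cells only that of stromal and endothelial markers had a positive median (0.29). The cell cycle list was also lower, with 0 of 52 genes past the threshold and 4 lower over the list alone (adjusted p = 0.0236 with an estimated correlation). Ribosomal protein genes had a median of 0.52 with 0 of 89 past the threshold and 24 higher over the list alone (adjusted p = 0.3 with an estimated correlation). Mitochondrially encoded genes had a median of 0.24 with 0 of 15 past it (adjusted p = 0.628 with an estimated correlation). Egr1 (-0.90) and Fos (-0.48) of the immediate early genes, Ldha (-0.82) and the adhesion and motility genes Rac2 (-0.90) and Itgb7 (-1.06) were also on the negative side and the protease gene Adam19 (0.71) on the positive. In all 55 of 17362 genes passed in edgeR's test with Benjamini-Hochberg adjustment, 22 positive and 33 negative, 24 of them receptor segments. Without spleen control replicate 3 222 passed and without spleen cKO replicates 1 and 2 29 and 31. Without lymph node control replicate 1 30 passed, without lymph node cKO replicate 1 35, and with the segments left out 17.

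Lymph node and spleen cDC1s differed far more than the genotypes did. In control mice the lymph node cells had lower cDC1 markers. Cd8a stood at 134 ± 10.9 against 1060 ± 119 CPM (log2 fold change -2.98 ± 0.09, n = 3 each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 5.97e-12). Clec9a changed by -3.27 ± 0.11 and Xcr1 by -1.76 ± 0.15. Fscn1, the actin-bundling protein of mature dendritic cells, rose by 1.73 ± 0.13, Mfge8 by 4.16 ± 0.13, Ccl5 by 1.64 ± 0.13 and Itgb8, part of the integrin that activates TGF-beta, by 3.35 ± 0.34. Ccr7 did not pass (-0.16 ± 0.08, adjusted p = 0.131). In cKO mice Cd8a changed by -2.27, Clec9a by -2.54, Xcr1 by -1.79 and Sirpa by -1.31. Mfge8 rose by 3.29 and Fscn1 by 1.48, and Ccr7 again did not pass (-0.18, adjusted p = 0.101).

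Of 29 cDC1 identity genes 20 fell and 1 rose in control mice, the exception being the transcription factor gene Zbtb46 (0.95 ± 0.12; list median -1.20; adjusted p = 0.000431 with an estimated correlation). In cKO mice 21 fell and 1 rose (adjusted p = 0.000169 with an estimated correlation). Of 21 MHC class II genes 15 fell and 4 rose in control mice (H2-Eb1 -1.83, Cst3 -1.67, Rfxank 1.47; adjusted p = 0.00841 with an estimated correlation). Of 32 immediate early and heat shock genes 28 fell and 1 rose (Nr4a3 -3.53, Hspe1 -2.41, Socs3 0.97; adjusted p = 0.000431 with an estimated correlation). Of 30 inflammatory cytokine and chemokine genes 14 fell and 6 rose, with Cxcl9 (-3.30) and Ccl4 (-3.13) lower and Csf1 (3.73) and Ccl5 higher (adjusted p = 0.0154 with an estimated correlation). Of 43 regulatory and Treg-inducing genes 20 fell and 8 rose, with the galectin genes apart (Lgals1 1.97, Lgals3 -2.22; adjusted p = 0.134 with an estimated correlation). CCR7-linked maturation went both ways, 25 up and 15 down of 50 (Zmynd15 1.53, Synpo2 1.58, the IL-12 subunit gene Il12b -1.27, Cd274 -1.29), and its median of 0.08 became -0.04 with the 20 most counted genes left out. Of 89 ribosomal protein genes 82 fell (adjusted p = 0.125 with an estimated correlation). Mitochondrially encoded genes had 13 of 15 lower in control mice (median -1.19; adjusted p = 0.434 with an estimated correlation) and 9 of 15 in cKO mice. Of 75 genes of oxidative phosphorylation 40 fell and 11 rose in control mice (adjusted p = 0.343 with an estimated correlation). Genes of glycolysis and hypoxia had 14 of 30 higher and 1 lower (Eno1 1.45, Adm 3.67; adjusted p = 0.152 with an estimated correlation).

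Markers of other cells moved with the tissue, and their cell of origin was not tested. Of 21 T cell markers 19 rose in lymph node (Trbc2 5.21, Lat 3.67; adjusted p = 0.00841 with an estimated correlation), and of 15 plasma cell markers 12 fell and 1 rose (Jchain -3.98, Igha -4.00; adjusted p = 0.000431 with an estimated correlation). Of 19 neutrophil and monocyte markers 12 fell and 1 rose (median -3.69 with genes at 0 set to their bound; Plac8 -3.35). Of 15 erythroid markers 5 fell and 3 rose (median 0 with genes at 0 set to their bound), with the beta globin gene Hbb-bs at least 1570-fold lower in lymph node. The basophil genes Mcpt8 and Prss34 were at least 73.6-fold and 96-fold lower. The keratin gene Krt14 had 126 counts in lymph node and 1 in spleen (84.4-fold, interval 14.9 to 3360), and the chemokine gene Ccl21a of lymph node stroma 135 and 2 (45.2-fold, 12.3 to 377). Nphs1 (8.77), Calm4 (6.82) and the fatty acid transport gene Slc27a3 (5.84) rose. Gp2 (-8.23), Fam71a (-5.22), Asb2 (-4.61), Abcg3 (-4.35), Ms4a1 (-4.16) and Trpm2 (-4.15) fell. The salivary genes Smr3a (at least 1040-fold), Amy1 (3220-fold, 1100 to 15600) and Chia1 (2120-fold, 724 to 10300) were higher in lymph node controls.

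In control mice 7169 genes passed, 3651 higher and 3518 lower in lymph node, and in cKO mice 5107, 2454 higher and 2653 lower. Groups did not overlap for 49.5% and 50.9% of genes, against 10% by chance. Of the 33 lists camera called 16 in control mice, of which 8 held with an estimated correlation, and 20 in cKO mice, of which 13 held.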

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

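The tests on V segments, on library sets, on the RNA of other cells and on scaling, and the bounds for the splits, were chosen only after the results they bear on were seen. The difference in the cKO effect between lymph node and spleen was tested by an interaction term, and 55 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The differences on the log2 scale were 1.37 for Spic, 1.08 for Nr4a3, 0.86 for Bcl2l11, 0.82 for Cers6 and 0.76 for Rel, and -13.01 for Amy1, -2.83 for Acap1, -2.69 for Ms4a4b, -1.35 for Tmem214 and -1.29 for Cnp. The value for Amy1, a salivary gene, rests in part on 3 counts over the spleen controls and is uncertain in size. Among 100 splits of the libraries 5 gave as many genes, the real one included, with 100 genes in the highest other, so chance is not excluded for this count. Without spleen control replicate 3 the count was 222, and without spleen cKO replicates 1 and 2, lymph node control replicate 1 and lymph node cKO replicate 1 it was 29, 31, 30 and 35.

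For the other counts the splits were too few, 10 each. In spleen the real split gave 106 genes and the highest other 0, with 1 split of 10 reaching the real count. Lymph node against spleen gave 7169 genes in control mice and 5107 in cKO mice. There 1 split each reached the real count and the highest other gave 0. Every other split mixed the tissues within a group, which raises the spread, so few calls were likely in advance. In lymph node cKO against control gave 79 genes and another split 141, so 2 of 10 reached the real count. That split put lymph node control replicate 2 with lymph node cKO replicates 1 and 3, which are the 3 lymph node libraries with over 60% even counts among counts from 1 to 10.

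A first pattern was the rise of macrophage genes with a fall of cDC1 genes in the EpoR+ fraction. RNA of macrophages mixed into that fraction, despite the sort as XCR1+CD8a+ cDC1s, would dilute all cDC1 genes to about the same degree, and of 637 abundant genes that fell only 0.63% lay below the floor of -1.59 on the log2 scale, as dilution would allow, although 23 abundant genes below it did not pass the test. Under dilution the fall of the cDC1 list would need 47.1% of the EpoR+ RNA to be from cDC1s. The 0.63% was computed only for the fit without a replicate block. A scaling factor moves all genes alike, so a scaling error as the whole cause was argued against by the cDC1 list median, which lay -0.95 from the median of the abundant genes (-0.13), with the upper quartile of the list at -0.67. A single cDC1 state that carries both sets of genes could give the same 0.63% and was not told apart by these libraries, for which staining of single EpoR+ cells for XCR1 and a macrophage protein would be the test.

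The second pattern was that V segments of antibody genes were alike within each group of spleen and lymph node libraries. Of V segments with at least 100 counts 0% were 10-fold apart between libraries of a group, against 34.6% between control and cKO libraries of the same tissue (182 of 716 comparisons in spleen, and 103 of 108 in lymph node from 10 to 15 segments per pair). Libraries made from 1 pool of cells per group could give this. Cells of separate mice for each library might part the segments within groups, which was not seen, but no libraries known to come from separate mice set that expectation. Within the lymph node groups the 0% rests on 6 to 8 segments per pair. Germline differences between control and cKO mice as the whole cause were argued against, since 53.3% of the V segments 10-fold apart between the genotypes in a tissue (8 of 15) went the other way in the other tissue. If the libraries shared a pool, their spread would be technical and the p-values would not speak for mice.

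The last pattern was a split of libraries across genotype, seen in even counts. The contrasts of libraries under and over 60% even counts correlated between lymph node control, lymph node cKO and spleen control with r of 0.235 or more, as a technical set of libraries would give, and -0.134 to 0.149 with contrasts among the spleen cKO libraries, which all lay over 60%. With the set as a term 76 of the 79 lymph node genes were still called, so the sets could not be the source of most of them. In spleen the term left 53 genes, 39 of them shared with the 106, and rests on 1 control, since all 3 cKO libraries and of the controls only replicate 3 lay over 60%, so set and genotype are nearly confounded there. Spleen control replicate 3 lay closer to the cKO libraries (chi-square per degree of freedom 45.0 to 80.6) than to control replicates 1 and 2 (210 and 178), and no biological explanation was tested.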

How the results depend on the processing

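The alternatives with genes of other cells or receptor segments left out, with both apart spleen controls left out and with the library set as a term were chosen only after the results were seen. Of values for named genes past the threshold 0 changed sign under any alternative, and 24 of 490 lost the call after TLI/ATS, 62 of 1058 for EpoR+, 123 of 381 for cKO in spleen, 72 of 360 in lymph node, 125 of 439 for the difference, and 34 of 2054 and 46 of 1792 for lymph node against spleen in control and cKO mice. Those named genes were picked for passing the threshold, some for the largest changes without overlap, so a change of sign was unlikely in advance. Of 192 list members that did not pass, 28 changed sign in 64 of 2965 values and 228 values passed.

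DESeq2 called 1414 genes for TLI/ATS, 549 and 177 for cKO in spleen and lymph node and 426 for the difference; no filter gave 436, 170 and 364 for these last 3. A replicate block, for libraries that the labels do not pair, gave 1264 for TLI/ATS, 5347 for EpoR+, 40 for cKO in spleen and 15 for the difference. For EpoR+ 3077 were higher and 2270 lower with the block, against 1864 and 742 without it. Deviations of same-numbered libraries correlated with r = 0.562 for EpoR+ and EpoR-, where 2 pairs force the mirror value -0.562 for the other numbers. For TLI/ATS and untreated r was -0.085, and in the spleen and lymph node set it was -0.188 to 0.115. With the segments left out 22, 49 and 17 genes passed for spleen, lymph node and the difference. With genes of other cells left out 302 passed for TLI/ATS, which fewer genes tested brings about in part. In spleen both apart controls left out gave 49 and the set term 53, and in lymph node a fit of only its 6 libraries gave 44.

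Leaving out 1 library gave 476 to 4908 genes for TLI/ATS, 1454 to 2600 for EpoR+, 31 to 379 for cKO in spleen, 51 to 72 in lymph node, 29 to 222 for the difference, and 5877 to 7014 and 3856 to 4496 for lymph node against spleen in control and cKO mice. Shifts of over 1.5 times came without TLI/ATS replicates 1 and 2 (4908 and 4679), without EpoR+ replicates 1 and 2 (1496 and 1454), and for cKO in spleen without control replicate 3 (379) and cKO replicates 1, 2 and 3 (33, 31 and 57). They also came in lymph node without control replicate 1 and without cKO replicate 1 (51 each), and for the difference without spleen control replicate 3 (222), spleen cKO replicates 1 and 2 (29 and 31), lymph node control replicate 1 (30) and lymph node cKO replicate 1 (35). A lone library left in a group was assumed to vary like the others. Without TLI/ATS replicate 1 or 2 the spread came from the untreated pair alone. Chi-square per degree of freedom was 17.5 in that pair and 365 in the TLI/ATS pair, so the larger counts rest on too small a spread. Values that did not pass the test changed sign at times: Cd8a after TLI/ATS ran from -0.20 to 0.07 and Sirpa from -0.23 to 1.52, and in the difference Xcr1 ran from -0.18 to 0.08 (0, 0.02, 0.03, 0.07 and 0.08 where positive or 0) and Ccr7 from -0.11 to 0.04 (0.03 and 0.04). With an estimated correlation 3 of 18 lists were called for TLI/ATS, 0 of 11 for EpoR+ (7 with fry), 3 of 15 for cKO in spleen, 0 of 7 in lymph node, 3 of 14 for the difference, 8 of 16 (31 with fry) and 13 of 20 for lymph node against spleen. Apart from the TLI/ATS replicates left out, the cause was not tested for these shifts. Depth limits Epor, which with no filter changed by -1.72 in spleen (adjusted p = 0.718) and -7.04 in lymph node (0.329) in edgeR's test with Benjamini-Hochberg adjustment.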

Other observations

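The tests of the EpoR lists across comparisons and the salivary, pancreatic and V segment values were chosen only after the results were seen. Macrophage RNA in the EpoR+ fraction was not told apart from a cDC1 state. The EpoR lists may therefore hold macrophage genes and diluted cDC1 genes, and their shifts do not by themselves show a response to EpoR. The 200 genes with the lowest p among those higher in EpoR+ cDC1s were followed in the treated cDC1s, where 37 of 193 tested rose and 8 fell after TLI/ATS (camera adjusted p over 12 tests = 4.27e-23; adjusted p = 0.222 with an estimated correlation). The 200 with the lowest p among those lower in EpoR+ cDC1s had 3 genes higher and 0 lower after TLI/ATS, with 153 of 200 positive and a median of 0.21. Camera called this list (adjusted p = 3.78e-05), but not with an estimated correlation (adjusted p = 0.335), and fry did not (adjusted p = 0.213). These 200 genes followed the tissue as well. They were lower in lymph node than in spleen, with 113 of 198 lower and 25 higher in control mice and 107 lower and 19 higher in cKO mice (adjusted p = 0.000368 with an estimated correlation in both). In lymph node 4 of the same 198 were higher in cKO libraries and 0 lower (adjusted p = 0.0155 with an estimated correlation), and in spleen 5 were higher and 0 lower (adjusted p = 0.142 with an estimated correlation). The effect on this list was not called different between the tissues (median difference -0.01; camera adjusted p = 0.389; adjusted p = 0.458 with an estimated correlation). For the list higher in EpoR+ cDC1s the cKO effect had a median of 0.15 in spleen (2 of 168 rose, 1 fell), -0.15 in lymph node (0 rose, 1 fell) and -0.34 in the difference (camera adjusted p = 0.0325, 0.0244 and 0.00312; adjusted p = 0.16, 0.154 and 0.0753 with an estimated correlation). Across all genes the TLI/ATS and EpoR+ changes were nearly uncorrelated (Pearson r = 0.067, Spearman -0.114). Yet 59 genes rose in both against 9.7 by chance, and 2 fell in both against 14.9. A further 64 fell after TLI/ATS and rose in EpoR+ cells against 32.7.

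Outside the receptor segments, Rad50 and Tpm2 were the 2 genes called for cKO against control in both tissues, both higher in each (0.54 and 0.89 in spleen, 0.86 and 1.43 in lymph node), against 0.1 such genes by chance. Loss of Epor itself was not detectable in spleen. The log2 fold changes for cKO in spleen and lymph node did not correlate across all genes (Pearson r = -0.025, Spearman -0.088). Only 106 and 79 of 17362 genes were called, so noise in the others weighs on this value and shared effects are not excluded. Of the 8 receptor segments called in both tissues 6 went opposite ways, such as Igkv10-96 at 1.49 in spleen and -10.43 in lymph node.

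Salivary gland genes summed to 782 to 1390 CPM in lymph node controls and to 1.19 to 3.15 CPM in lymph node cKO libraries, with group means of 0.83 and 1.15 CPM in spleen control and cKO. Pancreatic enzyme genes summed to 2640 and 186 CPM in the EpoR- libraries and to 113 and 89.2 CPM in the EpoR+ libraries. Between the TLI/ATS libraries 63 of 75 V segments with at least 100 counts were 10-fold apart and between the untreated libraries 0 of 69, while EpoR+ and EpoR- libraries parted in 0.7% of them.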
